A study of Mus musculus with 18 samples.

How the data were processed

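RNA was sequenced on the Ion Proton from hearts of adult mice that had sham surgery or ligation of the left anterior descending coronary artery at 8 to 10 weeks of age. RNA was taken 6 weeks after surgery. There are 18 libraries in 6 groups of 3. Whole-heart total RNA comes from infarcted hearts of control and Salv cKO mice. Cardiomyocyte RNA from translating ribosome affinity purification (TRAP), which pulls down tagged ribosomes with the RNA bound to them, comes from both genotypes after infarction and after sham surgery. Salv is Salvador (gene Sav1), an adaptor of the Hippo kinase pathway, and cKO stands for conditional knockout. The label "wild type control" is the submitters'. The labels do not say that the replicates of a group are separate animals, so the p-values measure the spread between these libraries.

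The deposited files hold raw counts per gene symbol, 1 library to a file, with 46983 symbols in each. A deposited table of the whole series held the same counts in all 18 columns. The submitters' processing notes name STAR 2.5, the mm10 genome and DESeq2. The counting tool, the annotation and the strand setting are not given in the sources used here. Library totals ran from 3240871 to 24135877 counts. A floor of 3 counts in 1 library corresponds to 0.124 to 0.926 CPM (counts scaled to the library total). Floors and intervals cover counting error only, since the reads carry no molecular identifiers.

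Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr, the robust quasi-likelihood fit and its two-sided test. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes tested are said to pass. The 12 TRAP libraries were fitted together (11393 genes), the 6 total RNA libraries together (12945 genes), and the 12 libraries of infarcted hearts together for TRAP against total RNA (13267 genes). No block was used, because the labels do not say that a replicate number marks a shared animal, batch or day. The mean correlation of residuals between TRAP libraries with the same number was -0.0017, which does not exclude pairing. Group levels are means ± SD of TMM-scaled CPM with n = 3 libraries, unless another unit is named. Fold changes are log2 values with their standard error (SE). For 3 libraries against 3, groups that do not overlap occur in 10% of genes by chance.

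The 8 comparisons were genotype in TRAP RNA after infarction and after sham, infarction in TRAP RNA of each genotype, genotype in total RNA after infarction, TRAP against total RNA after infarction, and 2 interactions (genotype by surgery, genotype by RNA fraction). The comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are Sav1, Park2, Yap1, Nppa, Nppb, Myh6 and Myh7 whatever their result. To these come up to 10 passing genes with the highest and 10 with the lowest fold change (5 for an interaction) at a mean log2 CPM of at least 3, whose groups of libraries do not overlap; the last condition was not asked for the interactions or for TRAP against total RNA. Up to 4 passing members of each gene list were added where the list was called or had 3 or more passing members. Symbols of predicted genes, clones, pseudogenes and small structural RNAs were counted but not named by this rule. Another 3 genes that the rule chose are not reported here, though the counts of named genes include them. For TRAP against total RNA only some of the list members chosen are printed, and the counts include all of them. Where fewer than 5 genes passed in a direction, the 3 with the smallest p of the rest are given as values that did not pass.

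The 27 gene lists hold 671 genes, 4 of them in more than 1 list. They cover Hippo components, YAP targets, cardiac stress, sarcomere, calcium handling and ion channels, the dystrophin complex, oxidative phosphorylation, fatty acid oxidation, glycolysis, mitochondrial quality control, antioxidant response, cell cycle, unfolded protein response, immediate early genes, nuclear noncoding RNA, the mitochondrial genome and ribosomal proteins. Others hold markers of fibroblasts and matrix, endothelium, leukocytes, mural cells, epicardium, adipocytes, Schwann cells, erythroid cells, and lung and airway, and genes of the sex chromosomes. The libraries are bulk RNA, so marker lists are read as levels. Lists with 5 or more genes tested were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each call was repeated with an estimated correlation, and fry tested whether a list's genes moved one way.

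On simulated data made from these libraries, with 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 23.7% to 46.4% of 2-fold changes in the comparisons of 3 libraries with 3. For 4-fold changes it recovered 76.3% to 91.8%. Of the genes called in these simulations 9.84% were false for genotype after infarction in TRAP RNA, 9.48% for infarction in control, 6.94% for genotype in total RNA, 5.04% for infarction in Salv cKO and 4.5% for genotype after sham, against a nominal 5%. For the interactions of genotype with surgery and with RNA fraction it was 6.76% and 2.78%. For 2-fold changes in the interactions, 8.25% and 9.18% were recovered. Alternatives were DESeq2 size factors within edgeR, the DESeq2 1.42.0 Wald test, no filter, a filter of 2 CPM in 3 libraries and a block on replicate number. In the fit of infarcted hearts the block was genotype with replicate number. The 2 groups fitted alone and each library left out in turn were alternatives too. Chosen after seeing the data were the fits without 2 sham libraries that held Y chromosome counts, fits with all TRAP libraries thinned to the smallest total (5 draws), and fits with trends of gene length and GC content removed. Near-identical copies were sought with BLAST+ 2.17.0 among annotated transcripts at 95% identity over at least 100 bases and 30% of the shorter transcript. Genome positions are those of the mm10 annotation. Splice forms, exon usage, variants and reads were not analysed here, since the files hold gene counts.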

Results

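Gene counts were compared in 18 libraries from mouse hearts. Total whole-heart RNA after infarction was sequenced in 3 libraries of control and 3 of Salv cKO. TRAP cardiomyocyte RNA was sequenced from 3 libraries each of control and Salv cKO after infarction and after sham surgery. Library totals were 24135877, 6451570 and 9168027 counts in total RNA control and 11051303, 6580318 and 6690915 in total RNA Salv cKO. In TRAP RNA they were 6706118, 6449748 and 5916285 in infarcted control and 7932292, 5901759 and 4335019 in infarcted Salv cKO. In sham TRAP RNA they were 3526334, 3752980 and 15902590 in control and 3240871, 3420112 and 4535562 in Salv cKO.

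Transcripts of the mitochondrial genome made up 15.8% to 29% of the counts in total RNA and 0.202% to 0.532% in TRAP RNA. The purification thus left few of them. Their differences within TRAP RNA may reflect how much was carried over, which was not tested. Control library 2 of total RNA held the lowest share of the 6, 15.8%. Genes of the Y chromosome had 567 counts in sham control library 2 and 659 in sham Salv cKO library 3, and at most 7 in each of the other libraries. All 12 libraries of infarcted hearts were in the latter class, so sex differed between libraries of the sham groups.

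Sav1, the gene targeted in the Salv cKO, lies on chromosome 12 from 69965012 to 69987002. Its level in TRAP RNA after infarction was 5.55 ± 1.16 CPM in control and 4.95 ± 1.28 in Salv cKO, and the fold change did not pass (log2 -0.15, SE 0.47, adjusted p = 0.986). After sham it was 6.31 ± 1.22 and 4.03 ± 4.15 CPM (log2 -0.57, SE 0.51, adjusted p = 0.596). The 3 sham Salv cKO libraries had 7, 3 and 34 Sav1 counts, or 2.16, 0.877 and 7.5 CPM of the library total, against 5.53 to 6.81 in sham control. Without sham Salv cKO library 1, 2 or 3 the log2 fold change was -0.31, -0.13 and -1.90 (adjusted p = 0.808, 0.937 and 0.0976), and library 3 is 1 of the 2 with Y chromosome counts. In total RNA it was 26.7 ± 3.25 and 21.6 ± 4.45 CPM (log2 -0.30, SE 0.21, adjusted p = 0.53). Between infarction and sham its log2 fold change was -0.16 in control (SE 0.48, adjusted p = 0.926) and 0.25 in Salv cKO (SE 0.51, adjusted p = 0.78), where it was -0.0125, -0.19 and 1.58 without sham Salv cKO library 1, 2 or 3 (adjusted p = 0.991, 0.839 and 0.0659). Sav1 was lower in TRAP than in total RNA (log2 -1.49, SE 0.19, adjusted p = 3.32e-07). The counts sum all exons, so a deletion of some exons would not have to lower them, and the genotype labels could not be checked from this gene.

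**Figure D1:**
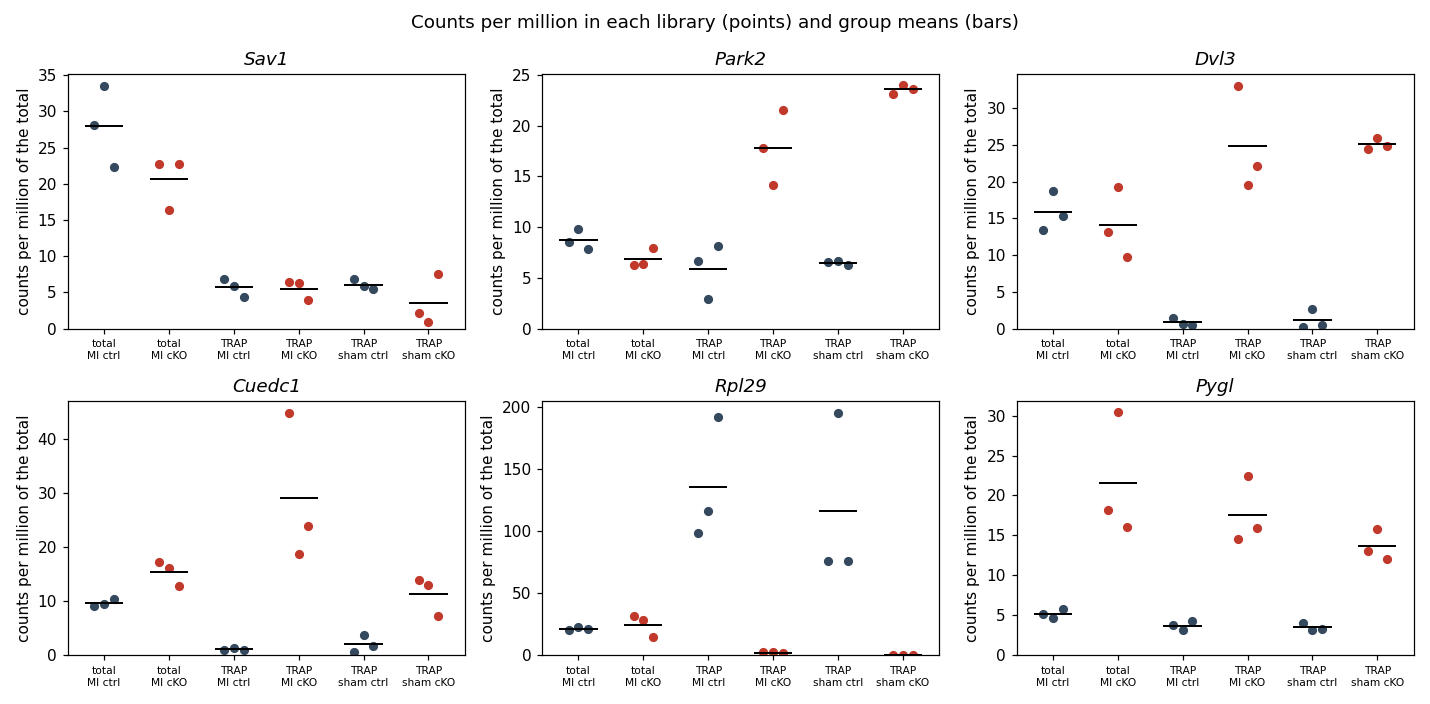
CPM of the library total for 6 genes, with 1 point per library, a bar at the mean of each group of 3 and Salv cKO in red. Sav1 libraries of the 2 genotypes overlap in TRAP RNA, whereas Dvl3 and Park2 are higher in every Salv cKO TRAP library than in every control TRAP library.

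The comparison of genotypes in TRAP RNA after infarction asks which transcripts differed between Salv cKO and control 6 weeks after ligation. Park2, which encodes Parkin, a ubiquitin ligase of mitophagy, rose from 5.77 ± 2.64 to 15.8 ± 3.1 CPM (log2 1.45, SE 0.30, adjusted p = 0.0342). Dvl3, a dishevelled protein of Wnt signalling, rose from 0.847 ± 0.517 to 22.2 ± 6.02 CPM (log2 4.66, SE 0.45, adjusted p = 4.11e-06), and Cuedc1 rose by 4.51 on the log2 scale (SE 0.45). The protease gene Tmprss13 (log2 3.22), the kinesin gene Kif5c (2.67), the glycogen phosphorylase gene Pygl (2.13), Olfml2b (1.94), the sorting receptor gene Sorl1 (1.67), the myosin light chain gene Myl4 (1.59) and Fig4 (1.02) rose too. The ribosomal protein gene Rpl29 fell from 132 ± 50.3 to 1.89 ± 0.406 CPM (log2 -6.07, SE 0.41, adjusted p = 6.91e-07). Zcchc3 (log2 -2.15), Fkbp10 (-1.53), Zfp945 (-1.47), Wdfy1 (-1.43), Crnde (-1.31), the fatty acid transporter gene Slc27a1 (-1.25), Dhrs7 (-1.17), Pcp4l1 (-1.12) and Ccdc85b (-1.08) also fell. Rpl29 has 34 near-identical copies and Zcchc3, Wdfy1 and Ccdc85b have 1 each. Summed with its copies, Rpl29 had a log2 fold change of -4.61 (adjusted p = 9.28e-05). Zcchc3 and Wdfy1 bring 100% of the counts summed with their copies, so a sum could not change them. mt-Nd3 had 50 to 78 counts in the Salv cKO libraries and 0 to 5 in control, and shares its sequence with the nuclear pseudogene Gm28438. The sum of both did not pass (log2 -0.68, SE 0.32, adjusted p = 0.664).

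In that comparison 21 genes were higher and 17 lower in Salv cKO among 11393 tested, and in all 38 the libraries of the genotypes did not overlap. Without control library 1, 2 or 3 or Salv cKO library 1 the count was 24, 22, 22 and 23, it was 58 with the 2 groups fitted alone, 72 with DESeq2 and 106 with no filter. Of 21 passing genes named here or by the lists, 10 passed whichever library was left out; Park2 did not without control library 1 or 2 or Salv cKO library 1 or 3 (highest adjusted p = 0.23). The separation share over all genes was 14.6% against 10% by chance. Of the passing genes with a genome position 7 of 37 (18.9%) are annotated pseudogenes, against 2.82% of tested genes (Fisher's exact test, p = 6.54e-05).

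Of 25 cell cycle genes tested in infarcted TRAP RNA, 23 had a positive fold change with a median log2 of 1.21; 6 rose when adjusted over the list alone, and by edgeR over all genes 0 passed (14 at an unadjusted p under 0.05, 0 by DESeq2). Camera placed this list above the other genes (adjusted p = 2.74e-11; adjusted p = 0.191 with an estimated correlation). Leukocyte markers had a median of -0.45 (adjusted p = 2.06e-04; adjusted p = 0.6 with an estimated correlation), with 3 of 24 positive. Ribosomal protein genes had a median of -0.20 (adjusted p = 4.86e-10; adjusted p = 0.6 with an estimated correlation), with 1 of 75 past the threshold, Rpl29, over all genes and over the list alone. Oxidative phosphorylation genes had a median of -0.16 (adjusted p = 5.01e-06; adjusted p = 0.6 with an estimated correlation), sarcomere genes -0.21 (adjusted p = 0.0306; adjusted p = 0.6 with an estimated correlation) and epicardial markers -0.81 (adjusted p = 0.0213; adjusted p = 0.394 with an estimated correlation). Genes of the mitochondrial genome had a median of 0.21 (adjusted p = 7.21e-04; adjusted p = 0.6 with an estimated correlation), with mt-Nd3 the 1 of 8 that passed. By edgeR 0 leukocyte, oxidative phosphorylation, sarcomere and epicardial genes passed over all genes (2, 13, 5 and 4 at an unadjusted p under 0.05, 0, 1, 1 and 0 by DESeq2), and 0, 1, 1 and 3 were lower adjusted over the list alone.

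Across 11007 genes the fold changes for genotype in infarcted TRAP RNA followed gene length and GC content (Spearman's rho 0.18 and -0.27). That comparison was not fitted with these trends removed. The other lists were not called there (adjusted p = 0.0537 to 0.989). The 20 Hippo components had a median of 0.12 and the 20 YAP targets of 0.03, and by edgeR 0 of either passed (1 and 2 at an unadjusted p under 0.05, 0 by DESeq2); adjusted over the list alone 1 Hippo component was higher and 0 YAP targets. Median log2 values were 0.06 for cardiac stress genes, -0.03 for calcium and ion channel genes, 0.03 for the dystrophin complex, 0.04 for fibroblast and matrix genes, -0.25 for endothelial and 0.01 for mural cell markers. They were -0.05 for fatty acid oxidation, 0.01 for glycolysis, -0.01 for mitochondrial quality control, where Park2 was the 1 of 33 that passed, -0.04 for antioxidant genes and -0.08 for the unfolded protein response. They were -0.09 for immediate early genes, 0.21 for nuclear noncoding RNA and -0.84 for 5 erythroid genes. Against the sign of the median, the camera direction was down for cardiac stress and mural cell genes and up for calcium and ion channel genes, and the mean was positive for calcium, mitochondrial quality control and antioxidant genes. Adipocyte and Schwann cell markers had 4 genes tested each, with medians of -0.18 and -0.15, and no list test. No lung and airway or sex-linked gene was abundant enough to be tested in TRAP RNA (0 of 9 and 0 of 5). Yap1 (log2 0.03, SE 0.25), Nppa (-0.46, SE 0.79), Nppb (-0.10, SE 0.70), Myh6 (-0.39, SE 0.50) and Myh7 (-0.72, SE 0.44) did not pass.

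After sham surgery the genotype comparison asks what differed between Salv cKO and control without infarction. Several of the same genes moved: Park2 rose from 6.69 ± 0.616 to 26.6 ± 1.3 CPM (log2 2.001, SE 0.31, adjusted p = 0.00131) and Dvl3 from 1.11 ± 1.21 to 28.4 ± 1.63 CPM (log2 4.88, SE 0.47, adjusted p = 3.81e-06). Tmprss13 (log2 2.82), Cuedc1 (2.67), Kif5c (2.34), Sorl1 (2.28), the stearoyl-CoA desaturase gene Scd4 (2.25), Pygl (2.09), Pstpip1 (2.03) and Nudt21 (1.68), which acts in polyadenylation, rose as well. Among the genes that fell were Zcchc3 (log2 -2.56), Ppia (-2.46), Lamtor3 (-2.42), Gng5 (-1.91), Cxx1a (-1.89), the phospholipid transporter gene Abcb4 (-1.81), the collagen gene Col14a1 (-1.77), the antigen peptide transporter gene Tap2 (-1.68) and the elongation factor gene Eef1a1 (-1.67). Rpl29 had a mean of 0.394 CPM in Salv cKO against 116 ± 58.6 in control. Ppia has 22 near-identical copies, Eef1a1 12, Gng5 6, and Lamtor3 and Nudt21 1 each. The copy of Lamtor3 is Gm5900, which rose (log2 4.10), and the sum of both had a log2 fold change of -0.47 (adjusted p = 0.183).

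Between sham Salv cKO and sham control 155 genes were higher and 136 lower, with libraries that did not overlap in 290 of the 291; over all genes 21% did, against 10% by chance. Without sham control library 2 or sham Salv cKO library 2 or 3 the count was 175, 104 and 105. It was 84 without the 2 libraries with Y chromosome counts, of which 63 were among the 291, 127 with the 2 groups alone, 602 with DESeq2 and 651 with no filter. Park2, Dvl3, Pygl, Sorl1, Tmprss13, Cuedc1 and 10 others of 32 named genes passed whichever library was left out. Of the passing genes with a genome position 15 of 282 (5.32%) are annotated pseudogenes, against 2.82% of tested genes (Fisher's exact test, p = 0.0164).

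The mitochondrial genome was the list that moved most in sham TRAP RNA. Of 8 genes tested 5 rose over all genes and 7 over the list alone, with a median log2 of 0.97 (adjusted p = 4.98e-10; adjusted p = 0.215 with an estimated correlation; fry adjusted p = 0.03). The complex I gene mt-Nd1 rose from 514 ± 200 to 1040 ± 160 CPM (log2 1.02, SE 0.24), mt-Co1 by 0.91 (SE 0.18) and mt-Cytb by 0.85 (SE 0.21). mt-Nd3 had 0 counts in all 3 control libraries and 14 to 43 in Salv cKO, at least 12.2-fold higher against 3 counts per library, and the list's median stayed 0.97 with mt-Nd3 at that bound. Summed with its copy Gm28438 it did not pass (log2 0.0132, SE 0.34, adjusted p = 0.989). Mitochondrial transcripts made up 0.459% ± 0.0745 of the counts in sham Salv cKO and 0.251% ± 0.0534 in sham control. The library with the lowest share of mitochondrial transcripts in Salv cKO, 0.383%, lay above the highest in control, 0.308%. In total RNA of infarcted hearts the share was 15.8% to 29%, so the purification removed most of these transcripts. A difference in carry-over between the sham groups cannot be told apart from one in expression.

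Among the nuclear genes for oxidative phosphorylation 4 of 77 fell, among them the ATP synthase genes Atp5g1 (log2 -0.75) and Atp5g2 (-1.91) and the complex II gene Sdhd (-1.29); adjusted over the list alone 4 were higher and 10 lower (median -0.04, adjusted p = 0.919). Genes of the unfolded protein response had a median of -0.36 (adjusted p = 0.00339; adjusted p = 0.215 with an estimated correlation; fry adjusted p = 0.03), and Creld2 fell (log2 -1.04); 7 of 21 were lower over the list alone. Fibroblast and matrix genes had a median of -0.56 (adjusted p = 0.0329; adjusted p = 0.993 with an estimated correlation), with 1 of 36 past the threshold, Col14a1, over all genes and over the list alone. Ribosomal protein genes had a median of -0.13 (adjusted p = 0.0329; adjusted p = 0.993 with an estimated correlation), and 7 of 75 fell, among them Rpl10 (log2 -0.98), Rps6 (-0.94) and Rpl35 (-0.91), with 2 higher and 12 lower over the list alone. These 3 have 11, 10 and 5 near-identical copies. By edgeR 0 Hippo components and 0 YAP targets passed (3 and 4 at an unadjusted p under 0.05, 1 and 0 by DESeq2), and 0 did over either list alone. Nppa (log2 -1.68, SE 0.84), Nppb (-1.47, SE 0.75), Yap1 (-0.49, SE 0.27), Myh7 (-0.33, SE 0.44) and Myh6 (0.27, SE 0.49) did not pass.

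The genotype effects after infarction and after sham shared 25 genes, 17 higher and 8 lower in both, where 0.286 and 0.203 would be shared if the calls were independent. They include Park2, Dvl3, Cuedc1, Pygl, Sorl1, Tmprss13, Kif5c, Fig4, Olfml2b, Rpl29, Zcchc3, Wdfy1, Dhrs7 and Pcp4l1. Each of the 38 genes past the threshold after infarction had the same sign after sham. Across 11393 genes Pearson's r between the fold changes was 0.183 and Spearman's rho 0.0421; genes are not independent replicates. Pygl and Dhrs7 lie on chromosome 12 within 0.235 and 2.68 Mb of Sav1.

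**Figure D2:**
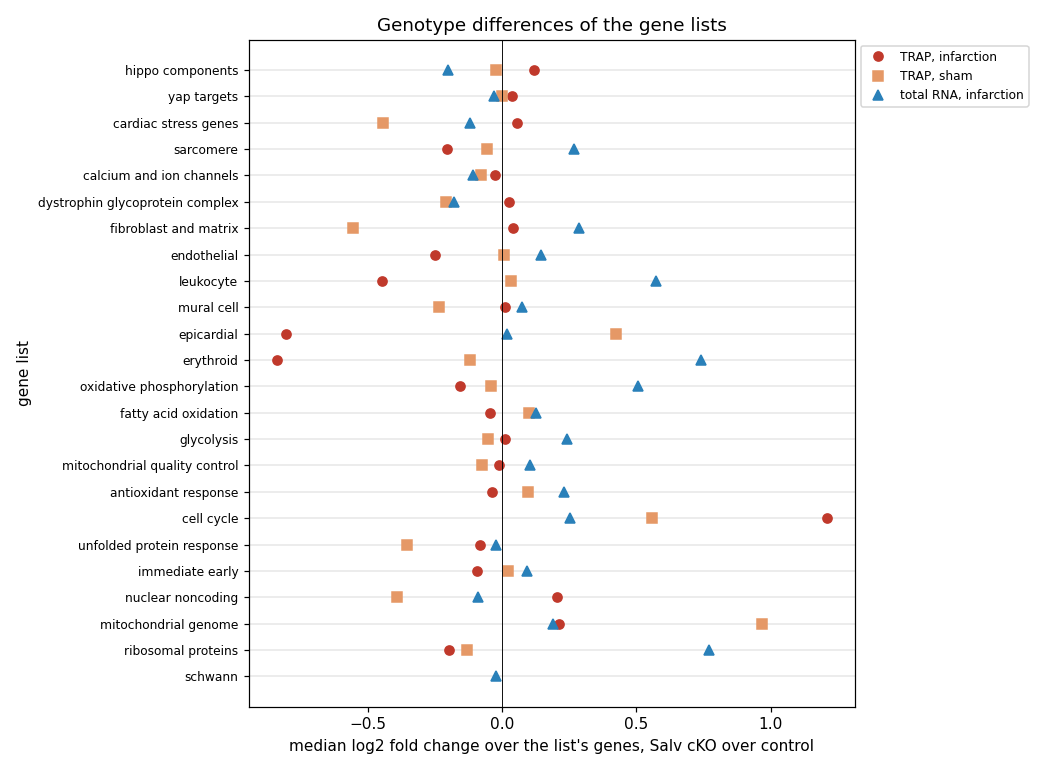
Median log2 fold change of Salv cKO over control for each gene list tested, in TRAP RNA after infarction (red circles), TRAP RNA after sham (orange squares) and total RNA after infarction (blue triangles). Cell cycle genes have medians of 1.21, 0.56 and 0.25, and ribosomal protein genes of -0.20, -0.13 and 0.77.

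Infarction against sham in control mice asks how TRAP RNA differed 6 weeks after ligation. Immunoglobulin transcripts rose, Igkc from 3.27 ± 2.37 to 30.6 ± 18.6 CPM (log2 3.32, SE 0.57, adjusted p = 0.0391) and Ighm by 2.01 (SE 0.45). These are transcripts of B cells rather than of cardiomyocytes. In total RNA of infarcted hearts Igkc had a mean of 88.4 CPM of the library total in control and 30.1 in Salv cKO. Carry-over from other cells into TRAP RNA was not tested. Igfbp4 (log2 1.48), Dda1 (1.26), the plectin gene Plec (1.07), the cofilin gene Cfl1 (0.999), Iah1 (0.99), Gmpr (0.87) and Rrad (0.78), which encodes a regulator of calcium channels, rose too. Ppara, the nuclear receptor that drives fatty acid oxidation genes, fell from 14.4 ± 7.73 to 3.84 ± 0.812 CPM (log2 -1.94, SE 0.43, adjusted p = 0.0391). Kin (log2 -2.17), the cohesin gene Smc3 (-1.83), Capn15 (-1.83), Rbm27 (-1.81), the splicing factor gene Cdc40 (-1.78), Lrif1 (-1.78), Baz2b (-1.74) and Tox3 (-1.74) fell. Nppa (log2 1.48, SE 0.81, adjusted p = 0.48), Nppb (0.95, SE 0.71), Myh7 (0.80, SE 0.44), Yap1 (0.73, SE 0.26), Myh6 (0.11, SE 0.49) and Park2 (-0.21, SE 0.32) did not pass.

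In control TRAP RNA 10 genes were higher and 113 lower after infarction; in 121 of the 123 the libraries did not overlap, as they did not in 19.1% of all genes (10% by chance). The count rested on single libraries: it was 0 without infarcted control library 1, 1 without infarcted control library 2, 6 without sham control library 1, 628 without sham control library 2 and 0 without sham control library 3 (1604 genes had an unadjusted p under 0.05 in the full fit). DESeq2 gave 462, no filter 566, a block on replicate number 408, removal of length and GC trends 0, equal depth 51 to 92, and the fit without the 2 libraries with Y chromosome counts 673, with all 123 among them. None of the 19 named genes passed whichever library was left out.

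Cardiac stress genes had a median log2 of 0.60 after infarction in control TRAP RNA (adjusted p = 0.00504; adjusted p = 0.642 with an estimated correlation), with 14 of 16 positive. Immediate early genes had a median of 0.70 (adjusted p = 0.015; adjusted p = 0.772 with an estimated correlation), and 4 were higher and 1 lower over the list alone. Fibroblast and matrix genes had a median of 0.17 (adjusted p = 0.014; adjusted p = 0.868 with an estimated correlation), sarcomere genes 0.17 (adjusted p = 0.0266; adjusted p = 0.642 with an estimated correlation) and epicardial markers 0.81 (adjusted p = 0.0266; adjusted p = 0.642 with an estimated correlation). By edgeR 0 members of these 5 lists passed over all genes; at an unadjusted p under 0.05 there were 0, 6, 3, 6 and 3, and by DESeq2 0, 3, 2, 4 and 1. Adjusted over the list alone 1 sarcomere gene was higher and 1 lower, 1 epicardial gene was higher, and 0 cardiac stress or fibroblast genes passed. Among Hippo components Map4k4 fell, the 1 of 20 that passed. Fold changes of this comparison followed gene length and GC content across 11007 genes (Spearman's rho -0.14 and 0.28).

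In Salv cKO TRAP RNA the same comparison of infarction with sham gave many more genes. On the first principal component of TRAP RNA (32.9% of the variance) the sham Salv cKO libraries lay at -37.6, -58.8 and -57.7. Sham control libraries lay at -17.9, 14.3 and -9.8, and infarcted libraries between 15.7 and 36.6. The sham side may thus account for part of the larger count. The extracellular matrix genes Comp (log2 3.72, SE 0.91) and Col14a1 (2.40, SE 0.39) rose, Col14a1 from 5.61 ± 2.43 to 28.9 ± 5.27 CPM. Igkc (2.82), Igfbp7 (2.73) and Dkk3 (3.03) rose as well. Matrix and immunoglobulin transcripts may be carried over from other cells, which was not tested. Yap1, the coactivator that Hippo kinases restrain, rose from 15.4 ± 5.26 to 36.4 ± 10.3 CPM (log2 1.25, SE 0.27, adjusted p = 0.00303), and so did 3 of 20 YAP targets, the tissue factor gene F3 (2.61), Cyr61 (1.65) and Igfbp3 (1.51). Over all genes 2069 of 11393 passed, so 3 of 20 is not more than the general share. Camera did not call the YAP target list in this comparison. Ppia (log2 2.91), Ppp1ca (2.73), Ube2s (2.72), the cytochrome c oxidase gene Cox5a (2.33) and Gng5 (2.27) rose. Capn15 (log2 -3.004), Frg1 (-2.84), Gnas (-2.53), Cngb3 (-2.38), Wdr70 (-2.36), Ccl24 (-2.29), the bicarbonate transporter gene Slc4a4 (-2.28), Hmgxb4 (-2.27), Zc3h6 (-2.23) and Med19 (-2.22) fell. The calcium release genes Ryr2 (log2 -2.12, SE 0.36) and Trdn (-1.63, SE 0.23) fell, Ryr2 from 4072 ± 1322 to 939 ± 195 CPM. Nppa (log2 2.69, SE 0.86, adjusted p = 0.0637), Nppb (2.32, SE 0.76, adjusted p = 0.069), Park2 (-0.75, SE 0.29, adjusted p = 0.0721), Myh7 (0.40, SE 0.44) and Myh6 (-0.54, SE 0.50) did not pass.

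Between infarcted and sham Salv cKO 861 genes were higher and 1208 lower; in 1995 of the 2069 the libraries did not overlap, as in 35.6% of all genes (10% by chance). The count was 1100 without infarcted Salv cKO library 1 and 1295 without sham Salv cKO library 3. Of 75 named genes 50 passed whichever library was left out, and Comp and Dkk3 were among the 25 that did not (highest adjusted p = 0.0958 and 0.15).

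Metabolic genes went both ways in that comparison. Of 77 oxidative phosphorylation genes 15 rose and 24 fell, such as Sdhd (log2 1.69), Atp5g2 (1.72) and Ndufa3 (-1.37), with 17 higher and 27 lower over the list alone (median -0.22). In glycolysis Eno1 (log2 2.01), Pgk1 (1.88) and Gapdh (1.46) rose, hexokinase Hk2 (-1.15) and 1 other gene fell, and the list alone gave the same 3 and 2. In fatty acid oxidation 5 of 28 rose, among them Fabp3 (1.45) and Esrra (1.26), and 4 fell, among them Etfb (-1.40) and Acot1 (-1.95); over the list alone it was 5 and 4. The antioxidant genes Gpx4 (1.44), Prdx1 (0.96), Prdx3 (0.81) and Sod2 (0.65) rose, 4 of 25 over all genes and over the list alone. Of 8 genes of the mitochondrial genome 4 fell, mt-Nd1 (-0.83), mt-Nd5 (-0.67), mt-Cytb (-0.64) and mt-Co1 (-0.55), and 5 over the list alone. Carry-over of mitochondrial transcripts could differ between the groups here too. In mitochondrial quality control Afg3l2 (0.85) and Map1lc3b (0.56) rose and Map1lc3a (-0.57) fell, with 2 and 0 over the list alone.

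Among structural and regulatory groups in Salv cKO, sarcomere genes gave 2 that rose, with Myom2 (log2 0.84), and 4 that fell, with Tcap (-1.22), Tnni3 (-0.79) and Myl3 (-0.61); over the list alone it was 2 and 4. Of 26 calcium and ion channel genes 3 rose and 5 fell, with Kcna5 (-1.19) among the latter, and over the list alone 3 and 5. The Hippo components Vgll4 (-1.61), Map4k4 (-1.29) and Wwc2 (-1.04) fell with 1 other, and Yap1 was the 1 that rose; over the list alone it was 3 and 5. In the unfolded protein response Creld2 (1.14), Atf6 (1.005) and Atf4 (0.80) rose with 1 other and Hsp90b1 (-1.05) fell with 1 other; over the list alone it was 6 and 3. Of 75 ribosomal protein genes 6 rose, such as Rpl10 (1.65), and 20 fell, such as Rps21 (-1.27), Rpl36 (-1.19) and Rps12 (-1.15), with 8 and 28 over the list alone. Gapdh and Rps12 have 24 near-identical copies each, Rpl36 8, Pgk1 4 and Eno1 3.

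Camera called 2 lists in this comparison. Fibroblast and matrix genes had a median of 0.995 with 33 of 36 positive (adjusted p = 3.37e-04; adjusted p = 0.859 with an estimated correlation); 4 rose, among them Comp, Col14a1 and Mgp (1.09), and Loxl2 (-1.43) fell, over all genes and over the list alone. Cardiac stress genes had a median of 0.80 with 14 of 16 positive (adjusted p = 0.00545; adjusted p = 0.859 with an estimated correlation); Fhl1 (1.12) and Rcan1 (1.03) rose, and 6 did over the list alone. Endothelial markers went both ways, with Robo4 (1.08) higher and Flt1 (-1.24) and Ptprb (-0.90) lower, as did mural cell markers, with Pdgfrb (1.18) higher and Vtn (-1.02) and Kcnj8 (-0.73) lower; adjusted over the list alone 2 and 4 endothelial and 1 and 2 mural cell genes passed.

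The infarction responses of the 2 genotypes, which share no library, had a Pearson's r of 0.458 and a Spearman's rho of 0.453 across 11393 genes, with a slope of 0.70 for Salv cKO on control. All 123 genes past the threshold in control had the same sign in Salv cKO. Of these 7 were higher and 93 lower in both genotypes, against 0.756 and 12 if the calls were independent, and 0 were opposite. Igkc, Igfbp4, Rrad, Gmpr, Dda1 and Cfl1 rose in both, and Capn15, Tox3, Baz2b, Lrif1, Map4k4 and Flt1 fell in both. Without the 2 libraries with Y chromosome counts r was 0.389, with 62 higher and 291 lower in both and 1 opposite.

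**Figure D3:**
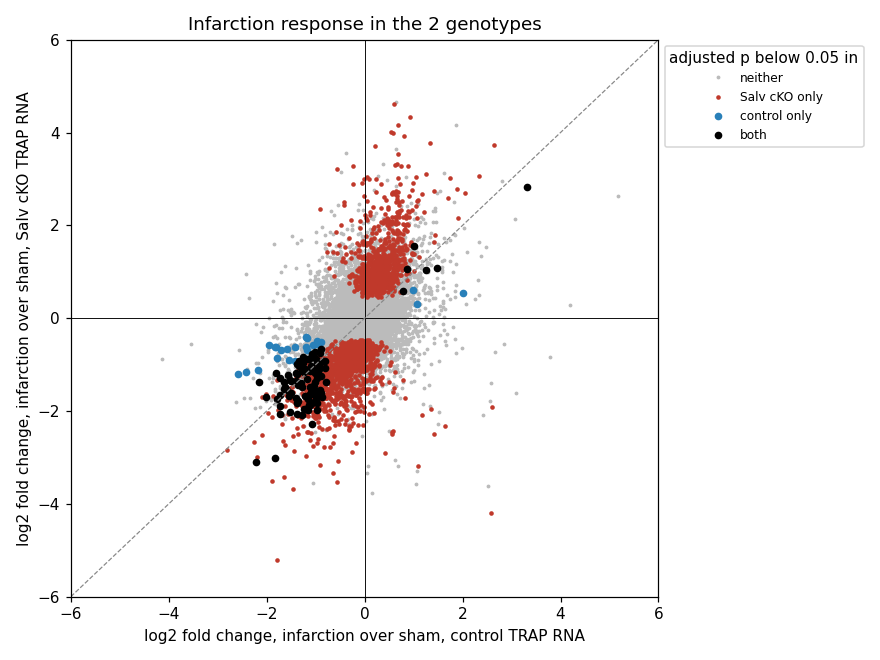
Log2 fold change of infarction over sham for each of 11393 genes in TRAP RNA of control (horizontal) and Salv cKO (vertical), with genes past the threshold coloured and 8 genes outside the axis limit of 6 not drawn. The dashed line marks equal changes, and the 100 genes past the threshold in both genotypes lie in the lower left or upper right.

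The genotype by surgery interaction tests directly whether infarction acted differently in Salv cKO. No gene passed with edgeR (0 of 11393, smallest adjusted p = 0.0796), while 1435 had an unadjusted p under 0.05 and DESeq2 gave 96. The smallest p on either side belonged to Gapdh (log2 of the ratio of fold changes 1.28, SE 0.24, adjusted p = 0.0796), Cxx1a (1.66, SE 0.40) and Rpl10 (1.16, SE 0.27), and to Kbtbd3 (-1.83, SE 0.33), Nudt21 (-1.76, SE 0.34) and Trim54 (-1.22, SE 0.24). Yap1 (log2 0.52, SE 0.37, adjusted p = 0.573), Nppa (1.22, SE 1.14), Nppb (1.36, SE 1.02), Park2 (-0.55, SE 0.43), Myh6 (-0.65, SE 0.70), Myh7 (-0.39, SE 0.61) and Sav1 (0.41, SE 0.70) did not pass either, so the larger number of genes in Salv cKO was not shown gene by gene to be a different response. The count was 18 without sham control library 1, 5 without sham Salv cKO library 1, 1 without infarcted Salv cKO library 3 and 160 with no filter.

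In total whole-heart RNA after infarction the genotype comparison covers all cell types of the heart. Pttg1, the securin of chromosome separation, rose from 2.38 ± 1.16 to 64.2 ± 14.7 CPM (log2 4.89, SE 0.37, adjusted p = 4.48e-05). Plekha7 (log2 2.56), Cyfip2 (2.54), Pygl (2.12), Sorcs2 (1.89), Mrps36 (1.68), Akr1e1 (1.57), Rpl11 (1.13) and the chemokine gene Cxcl14 (1.10) rose. The clock gene Per1 fell from 59.6 ± 8.02 to 19.4 ± 4.05 CPM (log2 -1.62, SE 0.21, adjusted p = 0.00329), with Zfp697 (-1.32), Zbtb16 (-1.27) and Chm (-1.10), the other named genes that fell. Park2 (log2 -0.24, SE 0.24), Yap1 (-0.16, SE 0.18), Nppa (-0.28, SE 0.81), Nppb (-0.38, SE 0.32), Myh6 (0.24, SE 0.32) and Myh7 (-0.43, SE 0.44) did not pass. Rpl11 and Mrps36 have 6 and 4 near-identical copies.

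In total RNA 24 genes were higher and 9 lower among 12945, and in all 33 the libraries did not overlap, as in 19.4% of all genes (10% by chance). The count was 17 without control library 1, 59 with a block on replicate number, 149 with DESeq2 and 363 with no filter. Pttg1, Plekha7, Cyfip2, Pygl and Per1 were the 5 of 13 named genes that passed whichever library was left out. Sorcs2 and Mrps36 did not without control library 1 (adjusted p = 0.113 and 0.0838). Of the 33 genes 12 (36.4%) are annotated pseudogenes, against 1.76% of tested genes (Fisher's exact test, p = 1.68e-13). The naming rule leaves these out, and reads shared with their copies were not tested for this count.

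Ribosomal protein genes were higher as a group in total RNA of Salv cKO. Their median log2 fold change was 0.77 with 69 of 75 positive (adjusted p = 5.3e-30; adjusted p = 0.452 with an estimated correlation), 1 passed over all genes, Rpl11, and 49 over the list alone. Their share of all counts was 1.33% ± 0.0115 in Salv cKO and 0.979% ± 0.0266 in control. Oxidative phosphorylation genes had a median of 0.51 with 69 of 77 positive (adjusted p = 1.57e-10; adjusted p = 0.835 with an estimated correlation), glycolysis genes 0.24 (adjusted p = 0.0319; adjusted p = 0.835 with an estimated correlation) and sarcomere genes 0.27 (adjusted p = 0.0183; adjusted p = 0.872 with an estimated correlation). Leukocyte markers had a median of 0.57 with 21 of 24 positive and 12 higher over the list alone (adjusted p = 1.06e-07; adjusted p = 0.56 with an estimated correlation). Erythroid genes had a median of 0.74 with 3 higher over the list alone (adjusted p = 6.25e-06; adjusted p = 0.56 with an estimated correlation), and fibroblast and matrix genes 0.29 (adjusted p = 0.0183; adjusted p = 0.929 with an estimated correlation). In these lists but the ribosomal one 0 genes passed by edgeR over all genes (26, 6, 7, 13, 4 and 5 at an unadjusted p under 0.05, and 3, 0, 0, 1, 3 and 0 by DESeq2, in the order given). Fold changes in total RNA followed gene length and GC content across 12496 genes (Spearman's rho -0.41 and 0.37). With these trends removed the medians were 0.40 for ribosomal protein and 0.17 for oxidative phosphorylation genes. Hippo components had a median of -0.20 and YAP targets of -0.03, neither list called (adjusted p = 0.267 and 0.326).

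TRAP RNA was compared with total RNA after infarction, averaged over the genotypes. Purification and other differences between the 2 kinds of library, such as trends with gene length and GC content, were not separated. Sarcomere transcripts were enriched, Tnni3 by log2 3.69 (SE 0.21), Tcap by 3.46, Myl2 by 2.83 and Tnnc1 by 2.68; 15 of 22 were higher and 4 lower (median 0.88, adjusted p = 0.00627; adjusted p = 0.676 with an estimated correlation). The highest ratios among named genes belonged to Usp50 (6.75), Rpl37rt (6.69), Ndufa3 (5.33), Ndufb7 (5.01), Scand1 (5.004), Ndufs6 (4.90), Ndufa2 (4.86), Fam221b (4.79), Etfb (4.76) and Timm13 (4.75). Rpl37rt, Usp50 and Fam221b have 3, 2 and 1 near-identical copies. Of 77 oxidative phosphorylation genes 71 were higher and 3 lower (median 2.44, adjusted p = 1.71e-26; adjusted p = 0.163 with an estimated correlation), and of 75 ribosomal protein genes 71 and 1 (median 2.92, adjusted p = 1.05e-33; adjusted p = 0.105 with an estimated correlation). Transcripts that stay in the nucleus or in mitochondria were depleted: Xist (log2 -9.40), Malat1 (-7.08), mt-Atp6 (-8.14), mt-Co3 (-8.04), mt-Co1 (-7.86), mt-Nd5 (-7.82), mt-Cytb (-6.50), mt-Nd2 (-6.13), mt-Nd6 (-5.70) and mt-Nd1 (-5.63). Anxa11 was lower too (-5.58), and Mat2a had 0 and 10 counts in TRAP RNA of Salv cKO and control against 353 and 850 in total RNA. Of 12 mitochondrial genome genes 11 were lower (median -6.21, adjusted p = 2.13e-11; adjusted p = 0.163 with an estimated correlation), as were 9 of 12 nuclear noncoding RNAs with 2 higher (median -2.62, adjusted p = 9.78e-05; adjusted p = 0.105 with an estimated correlation).

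Markers of other cell types were not depleted alike. Endothelial markers were 4 higher and 15 lower (median -0.94, adjusted p = 0.048; adjusted p = 0.692 with an estimated correlation), with Cdh5 at log2 -3.12 and Cldn5 at 1.90. Fibroblast and matrix genes were 6 higher and 21 lower (median -0.59, adjusted p = 0.0643), with Col3a1 at -2.50 and Postn at -2.46. Leukocyte markers were 8 higher and 10 lower (median 0.003, mean -0.12, adjusted p = 0.802), with Cd52 at 2.48, C1qa at 2.06, Ptprc at -2.77 and Ccr2 at -2.08. Epicardial markers were 1 higher and 6 lower, with Wt1 at -3.20, mural cell markers 3 and 6, with Rgs5 at -2.58, and erythroid genes 3 and 2, with Alas2 at -3.98. Hippo components were 3 higher and 14 lower (median -0.86, adjusted p = 0.0211; adjusted p = 0.163 with an estimated correlation), with Lats1 at -3.20, and mitochondrial quality control genes 20 and 6 (median 0.44, adjusted p = 0.00833; adjusted p = 0.623 with an estimated correlation), with Clpp at 3.26 and Fis1 at 2.80. Slc8a1 (-3.49), Dmd (-2.85) and the fatty acid oxidation genes Cpt1b (-6.57) and Acadvl (-4.17) were lower in TRAP RNA. Park2 (log2 0.99) and Myh6 (0.84) were higher, Yap1 (-0.65), Myh7 (-1.59) and Nppa (-2.09) lower, and Nppb (-0.59, adjusted p = 0.165) did not pass.

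Of 13267 genes 4558 were higher and 5289 lower in TRAP than in total RNA. The median over all genes was -0.15, and it was -0.16 with DESeq2 size factors in the same test. The DESeq2 Wald test, which keeps every gene with counts, had a median of 0.20 over its own set of genes. Fold changes followed gene length and GC content across 12795 genes (Spearman's rho -0.35 and 0.34), and this comparison was not fitted with these trends removed.

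The genotype by RNA fraction interaction tests whether the genotype effect after infarction differed between TRAP and total RNA. Among named genes Dvl3 differed most upward, with a log2 ratio of fold changes of 4.69 (SE 0.49, adjusted p = 8.22e-06): it was 1.14 ± 0.714 and 28.9 ± 7.86 CPM in control and Salv cKO TRAP RNA, and 12.3 ± 0.742 and 11.9 ± 3.88 in total RNA. Cuedc1 (3.72, SE 0.47), Zmym6 (3.74), Prune2 (1.86) and Mau2 (1.80) also had a higher genotype effect in TRAP RNA. Rpl29 (-6.43, SE 0.44, adjusted p = 4.72e-08), Arhgef19 (-2.41), Rpp25l (-2.27) and Mrps36 (-2.13) had a lower one. The haemoglobin gene Hba-a1 had a ratio of -3.72 (SE 0.58), and the leukocyte genes Cd52 and H2-Eb1 of -2.11 and -1.65. Park2 did not pass (1.67, SE 0.43, adjusted p = 0.0852), nor did Sav1 (0.13, SE 0.38), Yap1 (0.16, SE 0.30), Nppa (-0.21, SE 1.06), Nppb (0.25, SE 0.73), Myh6 (-0.65, SE 0.47) or Myh7 (-0.31, SE 0.58).

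As a group the ribosomal protein genes had a lower genotype effect in TRAP than in total RNA, with a median log2 ratio of -0.997 (adjusted p = 1.72e-35; adjusted p = 0.117 with an estimated correlation; fry adjusted p = 0.021). Of 75, 8 passed over all genes and 55 over the list alone, all lower, with Rps18 at -1.67, Rpl36 at -1.61 and Rpl11 at -1.54. Across 12795 genes the log2 ratios of this interaction followed gene length and GC content (Spearman's rho 0.35 and -0.37), and the interaction was not fitted with these trends removed. Among 13267 genes 19 had a higher and 38 a lower genotype effect in TRAP RNA. The count fell to 16, 30 and 21 without total RNA control library 1 or 2 or Salv cKO library 2, and rose to 140 without total RNA control library 3. It was 21, 17 and 17 without TRAP control library 1, 2 or 3, 26, 16 and 30 without TRAP Salv cKO library 1, 2 or 3, 19 with the paired block, 273 with DESeq2 and 302 with no filter. Dvl3, Cuedc1, Rpl29, Mrps36 and Arhgef19 were the 5 of 15 named genes that passed whichever library was left out.

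Across 10919 genes the genotype effects in TRAP and total RNA had a Pearson's r of 0.00563 and a Spearman's rho of -0.15. Pygl, Eif3j2, Tdpx-ps1 and Gm6969 were higher in Salv cKO in both fractions, against 0.0296 genes if the calls were independent; 0 were lower in both and 0 opposite. Pygl, on chromosome 12 from 70190811 to 70231488, thus rose in Salv cKO in TRAP RNA after infarction (log2 2.13), after sham (2.09) and in total RNA (2.12).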

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

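The tests of linked DNA, of shared reads, of a mitochondrial variant and of gene length and GC content were chosen after the results were seen. For the count of genes in Salv cKO the criterion for length and GC content was also revised after its value was seen, because a ratio to a control count of 0 decides nothing.

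The genotype effect differed between TRAP and total RNA in 57 genes by the interaction test, with log2 ratios of 4.69 for Dvl3, 3.74 for Zmym6, 3.72 for Cuedc1, 1.86 for Prune2 and 1.8 for Mau2. Lower in TRAP RNA were Rpl29 (-6.43), Hba-a1 (-3.72), Arhgef19 (-2.41), Rpp25l (-2.27), Mrps36 (-2.13), Cd52 (-2.11), Rps18 (-1.67), H2-Eb1 (-1.65), Rpl36 (-1.61) and Rpl11 (-1.54). In 1 of 100 splits of the libraries, drawn from 200, the count was that high, and this was the real one. The highest other split gave 17, and the real split gave as few as 16 with 1 library left out. Other splits mix the genotypes within a group, which widens the spread for any gene with a genotype effect. They therefore cannot decide whether chance accounts for the count of this interaction.

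By camera 6 lists differed in that interaction, and none of these calls held with an estimated correlation. Ribosomal protein genes had a median log2 ratio of -0.997 (adjusted p = 0.117 with an estimated correlation), leukocyte markers -0.992 (adjusted p = 0.244 with an estimated correlation) and erythroid genes -1.62 (adjusted p = 0.244 with an estimated correlation). Oxidative phosphorylation genes had -0.658 (adjusted p = 0.556 with an estimated correlation), sarcomere genes -0.644 (adjusted p = 0.605 with an estimated correlation) and cell cycle genes 0.767 (adjusted p = 0.605 with an estimated correlation). By edgeR 8, 2, 1, 0, 0 and 0 of them passed over all genes in that order, at an unadjusted p under 0.05 58, 15, 4, 33, 11 and 0, by DESeq2 29, 6, 1, 7, 1 and 0. Adjusted over the list alone 55, 14, 4, 17 and 9 were lower and 0 cell cycle genes passed.

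In the interaction of genotype and surgery in TRAP RNA camera called 7 lists, and none held with an estimated correlation. Median log2 ratios were 0.608 for fibroblast and matrix genes, -0.415 for leukocyte markers, -0.113 for oxidative phosphorylation, 0.545 for cell cycle and -0.783 for the mitochondrial genome (adjusted p = 0.94 with an estimated correlation for each of these 5). They were -1.07 for epicardial markers (adjusted p = 0.547 with an estimated correlation) and 0.194 for the unfolded protein response (adjusted p = 0.692 with an estimated correlation). With mt-Nd3 at its bound the mitochondrial median was -0.661. By edgeR 0 genes of any of these lists passed over all genes; at an unadjusted p under 0.05 there were 3, 4, 19, 3, 4, 3 and 5 and by DESeq2 1, 1, 5, 0, 0, 0 and 1, in the order given. Adjusted over the list alone 1 oxidative phosphorylation gene was higher and 3 lower. In the same way 3 epicardial genes were lower and 2 genes of the unfolded protein response higher. Across 11007 genes the log2 ratios followed gene length and GC content (Spearman's rho 0.12 and -0.22). The interaction was not fitted with these trends removed.

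A set of 25 genes, Park2 among them, differed between the genotypes in the same direction in TRAP RNA after infarction and after sham. Of the set 40% have a near-identical copy, against 18.2% of 1096 tested genes that were searched. For the other 15 genes, Park2, Dvl3, Cuedc1 and Pygl among them, the search found no copy with which reads could be shared. It covered the longest annotated transcript of each gene, so reads shared over shorter matches or with unannotated copies were not tested. Of the 10 with a copy, 6 lost over 50% of their log2 fold change when summed with their copies, 5 of them bringing under 50% of the sum. Rpl29 kept it (92.4% of the sum). Zcchc3, Wdfy1 and Gm10653 bring 100%, so the sum could not test them and sharing stays open for the 10 as a group. A stretch of linked DNA that differs between the genotypes may account for part of the set, since 8 of its genes have another within 5 Mb (median of random draws 3, permutation p = 0.0481), among them Pygl and Dhrs7 near Sav1, while all genes past the threshold had 15 against 7 after infarction (p = 0.011), 202 against 204 after sham (p = 0.65) and 9 against 6 in total RNA (p = 0.114), and 2 and 3 of 41 tested genes near Sav1 passed after infarction and after sham. For mt-Nd3 and Gm28438 a strain variant in the mitochondrial genome could move reads between copies. In TRAP RNA mt-Nd3 brought at least 55.6% of their sum in each Salv cKO library and at most 4.1% in control. In total RNA its share was 0.0807% to 0.133% in Salv cKO and 0.121% to 0.217% in control. A variant that goes with the genotype would shift reads there too. Total RNA thus argues against it for these 2 genes, and their difference in TRAP RNA stays unexplained. An effect of Salvador loss on these genes is the biological explanation and stays open. The copy criterion was made stricter after a broader one had been seen. Of the set, Pygl and Tdpx-ps1 also passed in total RNA after infarction. Mean CPM of the library total there was 15.8 in control and 14.1 in Salv cKO for Dvl3. It was 8.73 and 6.85 for Park2, 21.4 and 24.7 for Rpl29, but 3.38 and 24.1 for Gm5900. A difference between the genotypes in the preparation of TRAP RNA was not tested.

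More genes differed between infarction and sham in Salv cKO than in control TRAP RNA, 2069 against 123. The sham Salv cKO libraries stood apart on the first principal component (-37.6, -58.8 and -57.7). Whether the larger count comes from the sham side was not tested. At equal depth the lowest count in Salv cKO was 1908 against 51 to 92 in control, which argues against depth. With length and GC trends removed it was 2100, 1890 of them among the 2069, against 123 in control without and 0 with the correction (edgeR; 1521 at an unadjusted p under 0.05, 462 by DESeq2 without the correction), and Spearman's rho of the Salv cKO fold changes with length and GC content was 0.014 and -0.0072, which argues against those trends. Without the 2 libraries with Y chromosome counts it was 1546 against 673. Each sham group held 1 such library and the infarcted groups 0, so sex was balanced between the genotypes. The difference shrank without these libraries but remained, which does not decide how much of it goes with sex. Without sham control library 2 alone the control count was 628. On the first principal component that library lay at 14.3, and sham control libraries 1 and 3 at -17.9 and -9.8. An effect of this single library is thus not separated from one of sex. A stronger response in Salv cKO was not shown by the interaction test (0 genes by edgeR, 1435 at an unadjusted p under 0.05, 96 by DESeq2) and stays open.

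Ribosomal protein genes were higher in Salv cKO than in control total RNA, with a median log2 fold change of 0.769. Camera with an estimated correlation did not call the list (adjusted p = 0.452). By edgeR 1 of 75 genes passed over all genes (50 at an unadjusted p under 0.05, 26 by DESeq2). Lists matched on length, GC content and level had a median of 0.299, which leaves a difference of 0.47 and argues against these trends as the whole cause. With the trends removed the median was 0.402. The lowest median with a library left out was 0.614, which argues against a single library. A biological difference between the genotypes stays open as a hypothesis, since other technical causes, such as RNA quality, were not tested. Leukocyte and erythroid markers were higher in the same libraries too, and a difference in the mix of cells was not tested.

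Other splits of the 6 libraries are too few (10) for a share under 0.05 in 5 comparisons: the real count was the highest in 1 split each, 38 against 0 (genotype after infarction), 291 against 0 (genotype after sham), 123 against 1 (infarction in control), 2069 against 0 (infarction in Salv cKO) and 33 against 3 (total RNA). For TRAP against total RNA 1 of 100 splits, the real one, gave 9847 and the highest other 5792. The other splits mix the RNA fractions within a group, which widens the spread for any gene that differs between them. They therefore cannot decide whether chance accounts for this count. For genotype by surgery all 100 splits gave as many as the real 0 (edgeR; 1435 at an unadjusted p under 0.05, 96 by DESeq2), and the highest other gave 192. That split swaps the genotype labels in sham alone, so it tests the sum of the genotype effects after infarction and after sham, and the structure of the samples it points to includes their genotype.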

How the results depend on the processing

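The fits without the libraries with Y chromosome counts, at equal depth and with length and GC trends removed were chosen after seeing the data. Of 4931 values of named genes past the threshold under other settings, 4395 stayed past it in the same direction, 536 no longer passed and 0 reversed. Of 850 values of named genes that did not pass, 791 stayed so, 30 passed and 29 reversed; of 141 Sav1 values 9 reversed; of 172 counts and correlations 116 stayed within their limits. Where a value below differs, the cause was not tested. With no filter the counts were 106 for genotype in TRAP RNA after infarction, 651 after sham, 566 for infarction in control, 160 for genotype by surgery, 363 in total RNA and 302 for genotype by fraction. DESeq2 gave 72, 602, 462, 96, 149 and 273 in that order. A paired block gave 408 for infarction in control, 59 in total RNA and 19 for genotype by fraction, and Nppb reversed there to -0.151. With the 2 groups fitted alone genotype after infarction gave 58 and after sham 127. Without the libraries with Y chromosome counts genotype after sham gave 84 and infarction in control 673, Myh7 after sham was 0.367 and Nppa in genotype by surgery -0.398. At equal depth infarction in control gave 52, 81 and 51 in 3 of 5 draws; Sav1 was 0.0634 for genotype after infarction and 0.00897 for infarction in control in 1 draw each, and Yap1 -0.0451 and -0.0442 for genotype after infarction. With length and GC trends removed infarction in control gave 0 (edgeR; 1604 at an unadjusted p under 0.05 and 462 by DESeq2 without the correction), Sav1 0.00231 and Park2 0.0586 there, and in total RNA Yap1 was 0.0488 and Park2 0.071. Of 187 list tests 46 were calls; with an estimated correlation 0 of these remained, and with the paired block 45 did. Among genes past the threshold in either comparison r was 0.707 for the infarction responses and 0.452 for the genotype effects in the fractions; the latter was -0.00777 with a stricter filter.

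With each library left out in turn the counts were 22 to 35 for genotype after infarction, 104 to 378 after sham, 0 to 628 for infarction in control, 1100 to 2005 in Salv cKO, 0 to 18 for genotype by surgery, 17 to 45 in total RNA and 16 to 140 for genotype by fraction. The highest counts came without infarcted Salv cKO library 2 (35), sham Salv cKO library 1 (378 and 2005) and total RNA control library 3 (45), and the other extremes are named with the comparisons; r between the fractions ran from -0.000773 to 0.0598 and was lowest without total RNA Salv cKO library 1. Genes whose direction reversed did not pass in the full fit. For genotype after infarction Sav1 ran from -0.302 to 0.0292, Yap1 from -0.225 to 0.217 and Nppb from -1.02 to 0.241; after sham Myh7 from -0.67 to 0.377 and Myh6 from -0.0915 to 0.734. For infarction in control Myh6 ran from -0.216 to 0.588 and Park2 from -0.501 to 0.121, and Sav1 in Salv cKO from -0.188 to 1.58 and in genotype by surgery from -0.0255 to 1.74. In total RNA Nppa ran from -0.934 to 0.24, Myh6 from -0.0305 to 0.42 and Nppb from -0.657 to 0.107. For genotype by fraction Nppb ran from -0.669 to 0.591, Nppa from -0.72 to 0.461, Sav1 from -0.0334 to 0.315, Myh7 from -0.722 to 0.0628 and Yap1 from -0.099 to 0.365. At the smallest library total the counts were 26 to 34 against 38 for genotype after infarction, 251 to 303 against 291 after sham, 51 to 92 against 123 for infarction in control and 1908 to 1927 against 2069 in Salv cKO. Of simulated 2-fold changes 23.7% to 46.4% were recovered in the comparisons of 3 libraries with 3, so changes of that size can be missed.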

Other observations

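The genes in this part were chosen after their values were seen. Among clock genes in infarcted TRAP RNA Arntl, the activator of the clock, was higher in Salv cKO (log2 1.89, SE 0.399, adjusted p = 0.0361) and Tef lower (-0.91, SE 0.181, adjusted p = 0.0245), while Per1 (-1.18), Dbp (-1.85), Hlf (-1.31) and Cry2 (-0.84) did not pass. After sham Per1 (-1.03), Dbp (-2.16) and Tef (-0.57) did not pass (adjusted p = 0.109, 0.0856 and 0.0946), nor did Arntl (0.39, adjusted p = 0.661), Nr1d1 (0.54, adjusted p = 0.223) and Cry1 (0.32, adjusted p = 0.694). In total RNA Per1 fell (-1.62, adjusted p = 0.00329), and Arntl (1.21), Tef (-0.82) and Hlf (-0.78) did not pass (adjusted p = 0.173, 0.208 and 0.201). Nr1d1 was at 0.36 there (adjusted p = 0.428). The clock genes were not tested as a list, and the labels give no time of day.

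Pttg1 had 24, 23 and 28 counts in total RNA control and 819, 367 and 360 in Salv cKO. In TRAP RNA its libraries were mixed, with 768, 591 and 71 counts in infarcted control, 123, 712 and 697 in infarcted Salv cKO, 10, 44 and 1187 in sham control and 324, 443 and 445 in sham Salv cKO.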
